A study of Drosophila virilis and Drosophila willistoni and Drosophila miranda with 119 samples.

How the data were processed

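Messenger RNA was sequenced from 119 single embryos of 14 Drosophila species, 64 at stage 2 and 55 at stage 5. Each combination of species and stage held 3 to 7 embryos, and stage 2 and stage 5 embryos were different embryos. The values are FPKM (fragments scaled by transcript length and library size) of the authors, 1 value per gene, species and stage, in which the embryos of a group were already combined. That these values are FPKM was inferred from the tools named and from the range of the deposited values. Reads were trimmed with cutadapt, aligned with TopHat2 and quantified with Cufflinks, Cuffnorm and Cuffdiff, per the submitters' processing notes; their versions and the genome builds are not given in the sources used here. Per the labels, the samples of D. simulans, D. sechellia, D. santomea, D. persimilis and D. mojavensis at both stages and of D. virilis at stage 2 had been mixed with D. melanogaster material. The molecule is given as total RNA for D. pseudoobscura and D. miranda and as polyA RNA for the others, although the text on the library kit is the same for all. Part of the libraries, among them all those of D. pseudoobscura and D. miranda, were taken by the authors from earlier work, per the labels. The stage 5 samples of D. pseudoobscura and D. miranda are titled latest5 with a sex, and those of the other species stage5.

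A table of 3764 genes with an ortholog in each of the 14 species was the main table. A wider table of 17674 genes with an ortholog in any species held the same values for all 3764 genes of the main table, which was checked gene by gene; its column names sit 1 place to the right of their values and were read accordingly. Of the columns of each table, 27 were used and 1 was left out, so 2 columns in all: each table has a D. melanogaster stage 5 column, but the sample list used here has no stage 5 sample of that species, so these columns could not be tied to samples. D. melanogaster therefore entered the stage 2 comparisons only, and 13 species entered those with both stages. Gene symbols are those of the tables; 3106 of the symbols of the main table and 12881 of those of the wider table match current symbols. The D. santomea values are tied to D. yakuba gene identifiers. Reads of near-identical genes (the ribosomal proteins, slp1 and its neighbour) can be split between copies, so their values are uncertain.

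Because no column belongs to a single embryo, species are the replicates and the spread between embryos is not part of any test. The depth of the libraries is unknown, so no counting interval or detection floor is given. A value of exactly 0, which 2945 values of the main table have, can be a failed estimate, and such genes are said to be listed at 0. Changes were computed on the log2(FPKM+1) scale (pseudocount 1), which understates the change of mRNAs near or below 1. Species share ancestry, so they are not independent, and all p-values treat them as if they were except in the alternatives that use clades or the species tree.

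For the stage comparison, 3496 genes of the main table with a mean FPKM of at least 1 were tested. The difference of stage 5 minus stage 2 in each species was fitted with limma (version 3.58.1, eBayes with trend, two-sided, in R 4.3.3), with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05 and a mean change of at least 1. The melanogaster subgroup was compared with the obscura group in the same way, on the stage change and on the stage 2 and stage 5 levels after each column was centred on its median. With limma, gene lists were tested by camera with its preset correlation, by camera with an estimated correlation, and by fry. There were 23 lists: gap and terminal genes, pair-rule genes, zygotic dorsoventral genes, cellularization genes, sex determination genes, maternal axis genes, germ plasm genes, regulators of maternal mRNA, genome activation factors, cell cycle regulators, heat shock proteins, other early zygotic genes, dosage compensation genes, eggshell genes, yolk and fat body genes, muscle genes, neuron genes, gut genes, testis genes, ribosomal proteins, mitochondrial ribosomal proteins, proteasome subunits and respiratory chain subunits. Within a species, with 1 value per stage, genes with at least 2-fold differences were counted without a test. A gene at 1 FPKM or above at stage 2 was called maternal, one below 1 at stage 2 and at 1 or above at stage 5 zygotic-only, and one at 1 or above at stage 2 and below 1 at stage 5 cleared. Sets were compared between species by the Jaccard index, and levels by Spearman correlation over genes, which are not independent replicates. Both were tested by an exact two-sided sign-flip permutation over the 13 species, whose smallest p is 0.000244. Each pair of species enters the means of both its members, so the means are not independent and these p-values are a description. Similarity was set against the number of branches between species on a fixed tree by a Mantel test with 100000 permutations. A species-specific absence was an mRNA below 1 in 1 species and at 5 or above in every other species at that stage, and a species-specific presence was the reverse. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and, for the tree, ape 5.8.1.

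The groups, tests, thresholds, lists, alternative settings and the rule for naming genes were fixed before the data were examined. By that rule the stage comparison names the 10 called genes with the largest and the 10 with the smallest mean change among those that moved the same way in every species, and up to 4 members of each list with the largest absolute change. The clade comparisons name the 5 called genes with the largest and the 5 with the smallest difference among those whose clades do not overlap. For species-specific mRNAs, the 5 genes with the largest gap to the nearest other species are named for each stage and direction. A gene that this rule names is not reported here. Other genes named in the text were chosen after their values were seen. The list rule was applied again to the wider table after the data were seen, to genes with values in at least 10 species. The results of the main table were computed again, as far as each setting applied, with pseudocounts of 0.1 and 5, other filters and thresholds, rescaling to the same total, quantile normalization, median-centred differences, 1 mean per clade, phylogenetic least squares (limma on differences transformed by the tree), without each species, and without the 6 mixed species. In the last, D. virilis was left out at both stages, and D. pseudoobscura and D. miranda, for which mixing is not given, were kept. The stage changes of the wider table were computed again only without each species. Female and male stage 5 embryos could not be compared, because no column is given per sex.

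The limma fits were tested on simulated data with the real genes and spreads. Normal noise was drawn independently for each gene and species, so shared ancestry and correlation between genes were left out. The wrong calls below therefore do not show how often these would produce calls. In the stage comparison of 3496 genes, 94% of genes changed by 2 on the log2 scale and 100% of those changed by 4 were recovered, with 2 wrong calls. In the clade comparison of the stage change, also of 3496 genes, 67% and 96% were recovered, with 9 wrong calls.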

Results

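Stage 2 embryos precede zygotic transcription, so their mRNA comes from the mother. Stage 5 embryos are cellularizing blastoderms in which the zygotic genome is active. Levels of mRNA at these stages were compared in 14 Drosophila species, from 64 stage 2 and 55 stage 5 embryos in groups of 3 to 7 per species and stage. Each value is the authors' FPKM for a gene, species and stage. The embryos of a group are combined in that value, so species were the replicates, and 13 species had both stages. Of the 3764 genes with an ortholog in all 14 species, between 80.7% and 82.3% reached 1 FPKM at stage 2 in a species. The sequencing depth is unknown.

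The first question was how the mRNA pool changed from stage 2 to stage 5 across species. The largest rise was that of CG10035, by 11.18 ± 0.69 on the log2(FPKM+1) scale (SD, n = 13 species), from a median of 0.622 to 3347 FPKM. The mRNA of link rose by 11.11 ± 1.10, and that of the gap junction protein Inx3 by 9.60 ± 0.53, to a median of 1081 FPKM. Dtg, a target of Dpp signalling, rose by 9.15 ± 0.56, Ptr by 8.83 ± 0.58 and halo, which controls lipid droplet transport, by 8.67 ± 1.29. CG14317 rose by 8.57 ± 0.96, the nuclear protein gene dan by 8.46 ± 0.52, the odorant-binding protein gene Obp99a by 8.43 ± 1.62 and ci, the transcription factor of Hedgehog signalling, by 8.28 ± 0.51.

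The largest fall was that of osk, which directs germ plasm assembly, and it fell by 6.54 ± 1.11 (SD, n = 13 species), from a median of 421 to 2.31 FPKM. CG4991 fell by 6.48 ± 0.88 and aret, the translational repressor Bruno, fell by 6.25 ± 0.71, from 384 to 3.24 FPKM. CG10960 fell by 5.51 ± 0.67, dmGlut fell by 5.44 ± 0.66 and the tetraspanin gene Tsp74F fell by 5.27 ± 1.00. Ggt-1 fell by 4.90 ± 0.84, the ABC transporter gene E23 fell by 4.86 ± 0.82, the cell cycle gene gnu fell by 4.79 ± 1.72 and Pxt, a peroxidase-family gene of oogenesis, fell by 4.71 ± 1.76. All 20 of these genes moved the same way in 13 of 13 species, with limma adjusted p-values of at most 3.35e-08.

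In all, 1134 of the 3496 tested genes rose (32.4%) and 626 fell (17.9%), and 781 and 256 of these moved the same way in all 13 species. Of all tested genes, 1116 (31.9%) moved the same way in every species, where even and independent signs would give 0.0244%. The median change of all genes was 0.45 ± 0.08 (SD, n = 13 species), and the total FPKM of genes below 100000 was 2.62-fold higher at stage 5 in the median species. Higher genes made up 64.4% of the calls, but 45.5% (743 higher, 889 lower) when each species was centred on its median, 44.3% (635 and 797) after quantile normalization, and 16.1% (296 and 1537) when columns were brought to the same total of genes below 100000. With phylogenetic least squares, 456 of the higher and 71 of the lower calls remained, and the falls of gnu (-4.03, limma adjusted p = 0.118) and Pxt (-4.69, adjusted p = 0.179) were no longer called.

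The zygotic patterning genes rose together. All 5 measured genes of the gap and terminal list, which holds genes that lay out the first body regions, rose (5 adjusted over the list alone). They included Kr (6.90 ± 0.64, to a median of 149 FPKM), kni (5.55 ± 0.77), hkb (5.33 ± 0.82) and tll (5.30 ± 0.98). All 7 measured pair-rule genes, which set up the segments, rose (7 adjusted over the list alone), among them ftz (7.80 ± 0.54), prd (7.70 ± 0.66), opa (7.62 ± 0.80) and slp1 (6.57 ± 0.85). All 11 measured zygotic dorsoventral genes rose (11 adjusted over the list alone), led by the mesoderm genes twi (7.47 ± 0.70) and sna (7.06 ± 0.90), followed by net (6.94 ± 0.61) and the Dpp antagonist sog (6.45 ± 0.97). Each of the genes named here rose in 13 of 13 species. The camera adjusted p was 0.000317 for the gap and terminal genes, 3.43e-05 for the pair-rule genes and 1.29e-06 for the dorsoventral genes. With an estimated correlation these were adjusted p = 0.0284, adjusted p = 0.0588 and adjusted p = 0.0284, so the pair-rule call was lost.

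Genes of sex determination, cellularization and other early zygotic genes rose as well. All 6 measured sex determination genes rose (6 adjusted over the list alone), including the X chromosome counting gene sisA (6.87 ± 0.80), its autosomal counterpart dpn (6.25 ± 1.06), the switch gene Sxl (3.62 ± 0.82, from a median of 27.5 to 379 FPKM) and os (3.52 ± 0.46). All 3 measured cellularization genes rose (3 adjusted over the list alone): halo, Bro (6.99 ± 2.50) and slam, which is needed for the cleavage furrows (1.98 ± 1.94, higher in 12 of 13 species). All 3 measured other early zygotic genes rose (3 adjusted over the list alone). These were the transcription factor genes D (5.72 ± 1.11) and esg (4.11 ± 0.78), and E(spl)m8-HLH, whose median was listed at 0 at stage 2 and was 20.7 FPKM at stage 5. The camera adjusted p was 0.000511 for sex determination, 0.0517 for cellularization, which was not called, and 0.00851 for the other early zygotic genes. Cellularization was called higher with median-centred differences (camera adjusted p = 0.0238), with 1 mean per clade (camera adjusted p = 0.0189) and by fry (adjusted p = 2.14e-10). With an estimated correlation, sex determination had adjusted p = 0.0284 and the other early zygotic genes had adjusted p = 0.0573, which was not called. The rise of slam was not called with phylogenetic least squares (2.47, adjusted p = 0.466), and its change was -0.02 when columns were rescaled to the same total. The call of Sxl was lost under that rescaling alone (1.52, limma adjusted p = 0.238). A few values above 100000 FPKM dominate the same total. With the total of genes below 100000, slam was at 0.74 and not called (limma adjusted p = 0.168), while Sxl kept its call.

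**Figure D1:**
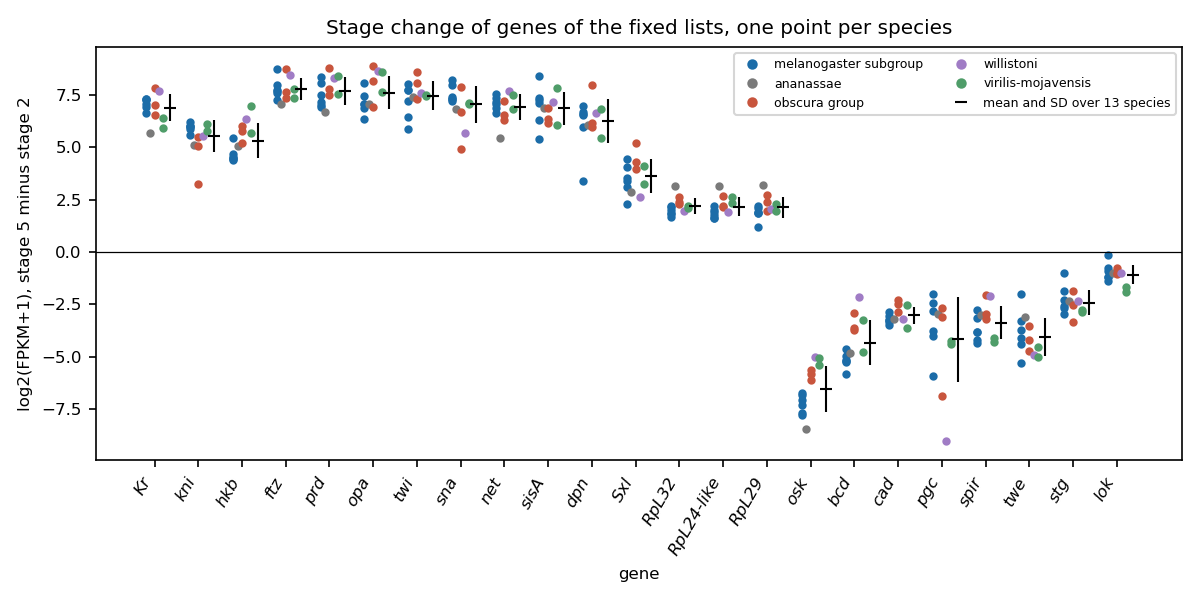
Change from stage 2 to stage 5 on the log2(FPKM+1) scale for genes of the fixed lists, 1 point per species, coloured by clade, with the mean and SD over 13 species as black marks. Zygotic patterning genes such as Kr (6.90) and ftz (7.80) lie far above 0 in every species, ribosomal protein genes near 2, and osk (-6.54) and bcd (-4.34) far below 0.

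Most measured maternal axis and germ plasm genes fell. Of the 8 measured maternal axis genes, 5 fell and 1 rose (5 and 1 adjusted over the list alone). Besides osk, the anterior determinant bcd fell by 4.34 ± 1.09 and cad fell by 3.03 ± 0.41. The gene that rose was cact, the inhibitor of Dorsal (1.66 ± 0.23), which was at -0.30 with columns rescaled to the same total. Of the 10 measured germ plasm genes 7 fell (7 adjusted over the list alone). Among them, the germ cell gene pgc fell by 4.18 ± 2.02, spir fell by 3.38 ± 0.80 and BicD fell by 2.93 ± 1.31. Of the 4 measured regulators of maternal mRNA 2 fell (2 adjusted over the list alone): gnu, and Fmr1, which fell by 1.88 ± 0.55. The change was -0.92 ± 0.69 for tral and -0.18 ± 0.79 for bel, and neither was called; tral was called lower with median-centred differences (-1.36, limma adjusted p = 2.84e-06) and bel after quantile normalization (-1.06, adjusted p = 0.000143). Of the 5 measured cell cycle regulators 3 fell (3 adjusted over the list alone): the Cdc25 phosphatase genes twe, which fell by 4.08 ± 0.91, and stg, which fell by 2.42 ± 0.59, and the checkpoint kinase gene lok, which fell by 1.08 ± 0.44. CycE was at 0.82 ± 0.87 and was not called, but it was called higher with 1 mean per clade (1.16, limma adjusted p = 0.00689).

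The camera adjusted p was 9.86e-05 for the germ plasm genes, 0.0111 for the maternal axis genes, 0.0109 for the regulators of maternal mRNA and 0.0252 for the cell cycle regulators. With an estimated correlation the germ plasm genes had adjusted p = 0.0284, while the other lists were no longer called, with adjusted p = 0.113 for the maternal axis genes, adjusted p = 0.0861 for the regulators and adjusted p = 0.0668 for the cell cycle regulators. With phylogenetic least squares, the falls of pgc (-4.93, limma adjusted p = 0.114), BicD (-2.34, adjusted p = 0.228), Fmr1 (-1.68, adjusted p = 0.0861) and lok (-1.20, adjusted p = 0.0857) were no longer called.

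All 37 measured ribosomal protein genes rose (37 adjusted over the list alone), from a list median of 1168 to 4372 FPKM, with a median change of 2.00. RpL32 rose by 2.20 ± 0.39, RpL24-like by 2.17 ± 0.44 and RpL29 by 2.13 ± 0.49. The list, called the ribosomal protein genes here, holds RpL24-like and RpLP0-like, whose symbols mark them only as similar to ribosomal proteins. The list lay above the median of all genes in 13 of 13 species and had a camera adjusted p of 3.62e-12, but an adjusted p = 0.154 with an estimated correlation. Its median change was 1.55 with median-centred differences, 0.65 with columns brought to the same total of genes below 100000, and 0.07 after quantile normalization, and under the last pair no member was called.

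Of the 18 measured proteasome subunits 9 rose (9 adjusted over the list alone), with a list median of 0.93, which turned to -0.46 after quantile normalization and -0.38 with the total of genes below 100000. They included the core subunit genes Prosbeta7 (1.94 ± 0.31), Prosbeta4 (1.43 ± 0.41), Prosbeta1 (1.43 ± 0.52) and Prosbeta2 (1.34 ± 0.49). Of the 43 measured mitochondrial ribosomal protein genes 7 rose (7 adjusted over the list alone), with a list median of 0.50, which turned to -0.78 with the total of genes below 100000. The largest changes were those of mRpS6 (1.45 ± 0.55), mRpS33 (1.44 ± 0.57), bonsai (1.44 ± 0.58) and mRpS2 (1.41 ± 0.33). Of the 3 measured respiratory chain subunits 1 rose (1 adjusted over the list alone), SdhC (1.26 ± 0.95), while SdhB (0.52 ± 1.07) and SdhA (-0.68 ± 0.79) were not called, although SdhA was called lower with median-centred differences (-1.12, limma adjusted p = 0.000151). The median of this list was 0.52 and its mean 0.37, yet camera gave it the direction down; its median turned to -0.14 after quantile normalization. With phylogenetic least squares, mRpS6 (1.34, limma adjusted p = 0.0774), mRpS33 (1.56, adjusted p = 0.177), bonsai (1.57, adjusted p = 0.190) and SdhC (1.19, adjusted p = 0.387) were no longer called. None of these lists was called as a set by camera, with adjusted p = 0.200 for the proteasome, adjusted p = 0.192 for the mitochondrial ribosome and adjusted p = 0.925 for the respiratory chain. Fry sets a list against no change rather than against the other genes, so a rise of all genes enters it. It called the proteasome (fry adjusted p = 2.34e-06) and the mitochondrial ribosome (2.56e-08) higher, but not the respiratory chain (0.113). With median-centred differences these were 0.000938, 0.0155 and 0.391.

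Heat shock genes moved both ways: of 3 measured, 2 fell and 1 rose (2 and 1 adjusted over the list alone), and the list was not called (camera adjusted p = 0.265). The mitochondrial chaperone gene Hsc70-5 fell by 2.97 ± 1.63 and the endoplasmic reticulum chaperone gene Hsc70-3 fell by 1.73 ± 1.02, both not called with phylogenetic least squares (-2.32, limma adjusted p = 0.238, and -1.56, adjusted p = 0.382). Hsc70-4 rose by 1.46 ± 0.54 but was at -0.29 after quantile normalization, and it was not called with phylogenetic least squares (1.48, limma adjusted p = 0.150). Of the 2 measured dosage compensation genes 1 rose (1 adjusted over the list alone), the helicase gene mle (2.09 ± 0.68), and msl-3 (0.31 ± 0.48) was not called. The call of mle was lost with phylogenetic least squares (1.96, limma adjusted p = 0.157), with the same total (0.12) and with the total of genes below 100000 (0.80); the median of the pair, 1.20, turned to -0.10 with the total of genes below 100000. The 1 measured genome activation factor, Stat92E (0.08 ± 0.93), and the 1 measured eggshell gene, Fcp3C (0.27 ± 0.49), were not called. No yolk, muscle or gut gene of the lists was in the main table; its 1 neuron gene, fne, and 1 testis gene, aly, had a mean below 1 FPKM and were not tested.

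The wider table, with 7214 genes that had values in at least 10 species, gave 2228 higher and 1189 lower genes. There, 9 of 10 gap and terminal genes rose, with gt at 6.05 ± 0.47 (SD, n = 11 species), and cnc fell by 1.21. All 13 pair-rule genes rose, including odd (6.70 ± 0.53, n = 12 species), as did all 21 dorsoventral and all 7 cellularization genes, including Sry-alpha (8.07 ± 1.37, n = 13 species) and Z600, with a median listed at 0 at stage 2 and 658 FPKM at stage 5. Of 8 sex determination genes 6 rose. Of 14 other early zygotic genes 12 rose (13 adjusted over the list alone), among them SoxN (5.82 ± 1.89, n = 12 species) and Ance (5.36 ± 1.31, n = 11 species), and nrv1 fell by 4.14. Of 18 maternal axis genes 11 fell and 1 rose; the Dorsal transcription factor gene dl fell by 4.55 ± 0.58 and the terminal receptor gene tor fell by 4.20 ± 0.57 (n = 12 species each). Of 20 germ plasm genes 14 fell, among them swa, which fell by 6.11 ± 1.22 (n = 10 species), BicC, which fell by 5.91 ± 2.28 (n = 13 species), and exu, which fell by 5.00 ± 1.75 (n = 12 species). Of 14 regulators of maternal mRNA 9 fell; orb fell by 3.73 ± 1.34, the kinase gene png fell by 3.6 ± 1.26 and smg, the repressor that destabilizes maternal mRNA, fell by 3.46 ± 0.46 (n = 12 species each).

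Also in the wider table, 3 of 7 genome activation factors rose and 1 fell: Trl, which encodes GAGA factor (1.75 ± 0.56, n = 11 species), Psc (1.29 ± 0.82, n = 12 species) and vfl, which encodes Zelda (1.23 ± 0.59, n = 10 species), while CBP fell by 1.21 ± 1.31 (n = 11 species). The symbol CBP can also stand for a gene that is no genome activation factor, so its place in this list is uncertain. Of 72 mitochondrial ribosomal protein genes 11 rose, with mRpL51 at 1.68 ± 0.71 (n = 11 species), of 30 proteasome subunits 12 rose, with Prosbeta5 at 1.63 ± 0.32 (n = 11 species), and all 77 ribosomal protein genes rose. Of 60 respiratory chain subunits 44 rose, among them COX7C (2.09 ± 0.43, n = 11 species) and ND-49 (2.03 ± 0.56, n = 10 species), and this list was called upward by camera (adjusted p = 2.05e-06). Of 9 heat shock genes 6 fell and 2 rose; Hsp26 fell by 4.78 ± 1.07 (n = 11 species) and Hsp27 fell by 4.36 ± 3.05 (n = 10 species), and this list, not called in the main table, was called downward (camera adjusted p = 0.0238). Of 15 cell cycle regulators 5 rose and 5 fell, with trbl at 3.64 ± 0.85 (n = 11 species) and CycB3 at 2.00 ± 0.18 (n = 12 species) among the higher, and the call of this list was lost (camera adjusted p = 0.394). The cellularization list, not called in the main table, was called upward (camera adjusted p = 0.000985). Of 4 dosage compensation genes only mle rose; msl-1 was at -0.85 ± 0.72 and mof at -0.25 ± 1.34 (n = 12 species each). Of the lists for other cells, 2 of 4 muscle genes rose, Tm1 (1.79 ± 0.46), which was also maternal with a median of 147 FPKM at stage 2, and Mlp84B (1.54 ± 1.06; n = 12 species each), and bt (0.58 ± 1.08) and TpnC41C (0.56 ± 1.06; n = 11 species each) were not called. The neuron gene elav rose by 4.54 ± 1.53 (n = 11 species). The testis gene gdl fell by 1.94 ± 2.79 (n = 11 species; limma adjusted p = 0.0316), a call lost when any of 5 species was left out, with adjusted p-values from 0.0662 without D. pseudoobscura to 0.0730 without D. ananassae. The yolk gene Yp3 (0.59 ± 0.79, n = 12 species) and the eggshell gene Cp7Fa (-0.04 ± 0.93, n = 13 species) were not called, nor was the eggshell gene yellow-g2, with a median listed at 0 at stage 2 and 0.0232 FPKM at stage 5, and no gut gene was measured. Unless given, the counts adjusted over the list alone equalled these. The list tests given here used the preranked form of camera, on 1 z-score per gene, at the preset correlation. Neither an estimated correlation nor fry was run with them, and with an estimated correlation several lists of the main table lost their call. The scalings were not run on the wider table, and in the main table changes of the size of those of vfl, Psc, Trl or the respiratory chain subunits lost their call under them, such as those of Prosbeta2 (1.34, but -0.20 after quantile normalization) and cact (1.66, but 0.10).

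The same question was asked species by species. Genes at least 2-fold higher at stage 5 numbered 1171 in D. simulans to 1391 in D. miranda (1305 ± 63.0, SD, n = 13 species), and genes at least 2-fold lower 641 in D. pseudoobscura to 856 in D. simulans (736 ± 64.6). With 1 value per species and stage, there was no test within a species.

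Classed by a threshold of 1 FPKM, all 5 measured genes of the gap and terminal list were zygotic-only in all 13 species. So were 6 of 7 pair-rule genes and 7 of 11 dorsoventral genes, all below 1 at stage 2 and at 1 or above at stage 5. The gene hb, also a gap gene but counted with the maternal axis genes, was maternal in all 13 species. All 37 ribosomal protein genes, 10 germ plasm genes and 8 maternal axis genes of the main table were maternal in every species. A species had 3070 ± 17.9 maternal genes (SD, n = 14 species; 81.6%), 338 ± 24.6 zygotic-only genes and 120 ± 20.6 cleared genes (n = 13 species). The number of zygotic-only genes ran from 287 in D. willistoni to 376 in D. virilis, and that of cleared genes from 94 in D. willistoni to 162 in D. simulans. Maternal mRNA of 2710 genes (72.0%) was present in all 14 species, and 309 genes were maternal in none. Only E23 and CG16711 were cleared in all 13 species. The median number of cleared genes, 119, was 77 at a threshold of 0.5 FPKM and 313 at 5 FPKM. The classes use unscaled FPKM with the same threshold at both stages. The total FPKM of genes below 100000 was 2.62-fold higher at stage 5 in the median species. How far this shifts the numbers of zygotic-only and cleared genes was not tested, as the classes were not computed with rescaled columns.

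**Figure D2:**
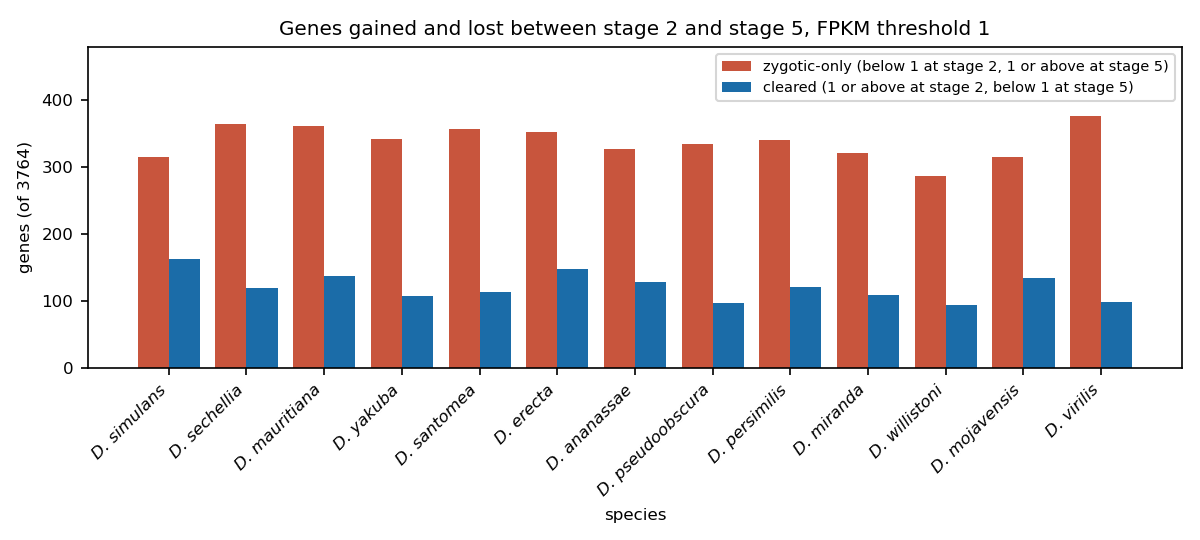
Number of zygotic-only genes (red) and cleared genes (blue) of the 3764 genes in each of 13 species, at a threshold of 1 FPKM. In unscaled FPKM, zygotic-only genes outnumber cleared genes in every species. They number from 287 in D. willistoni to 376 in D. virilis.

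Which set of genes was shared more between species was asked next. The maternal set was shared more: the mean Jaccard index of a species with the others was 0.932 for maternal genes and 0.457 for zygotic-only genes, a difference of 0.475 ± 0.0218 (SD, n = 13 species; exact sign-flip p = 0.000244, the smallest the test allows; higher in 13 of 13 species). Of the genes maternal in any of the 13 species, 78.6% (2714 of 3451) were maternal in all. Of the genes zygotic-only in any species, 9.96% (83 of 833), among them Dtg, halo, ci, Kr, ftz and twi, were zygotic-only in all. Large sets overlap more by chance, with 0.689 and 0.0469 as the indices of independent sets. Taking chance overlap off, kappa was 0.809 against 0.588, a difference of 0.220 ± 0.0138 (exact p = 0.000244). The means of the species share pairs and ancestry, so both p-values are a description only.

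The levels of the 3496 tested mRNAs were also more alike between species at stage 2. The mean Spearman correlation of a species with the others was 0.804 ± 0.0283 at stage 2 and 0.748 ± 0.0311 at stage 5 (SD, n = 13 species). The difference was 0.0564 ± 0.0102 (exact sign-flip p = 0.000244), higher at stage 2 in 13 of 13 species and in 77 of 78 pairs. As the means share pairs and ancestry, this p is a description too. D. yakuba and D. santomea were the closest pair at both stages (0.938 and 0.908), and the lowest values were those of D. mauritiana with D. miranda at stage 2 (0.696) and of D. erecta with D. miranda at stage 5 (0.630). Within a species, stage 2 and stage 5 correlated at 0.535 in D. erecta to 0.617 in D. miranda. D. santomea values rest on D. yakuba gene identifiers.

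Species with fewer branches between them on the tree had more similar mRNA pools. Over 91 pairs of 14 species, similarity at stage 2 fell with the number of branches between the species, with a Mantel Spearman correlation of -0.577 (permutation p = 5e-05, adjusted 0.0001) and a Pearson correlation of -0.550 (p = 2e-05, adjusted 4e-05). Over 78 pairs of 13 species, the values at stage 5 were -0.493 (permutation p = 0.0003, adjusted 0.0003) and -0.544 (p = 6e-05, adjusted 6e-05); 2 stages were tested. Without D. virilis and D. mojavensis, Pearson correlations were -0.526 (permutation p = 0.00027) and -0.550 (p = 0.00037). Among species not labelled as mixed with D. melanogaster at either stage, which include D. pseudoobscura and D. miranda, for which mixing is not given, the Spearman correlation was -0.462 at stage 2 (permutation p = 0.0196, n = 8 species), but the Pearson correlation was -0.393 and did not pass (permutation p = 0.0638). At stage 5 neither passed, at -0.291 (permutation p = 0.243, n = 7 species) and -0.297 (permutation p = 0.227). The number of branches is not a measure of time since species split.

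**Figure D3:**
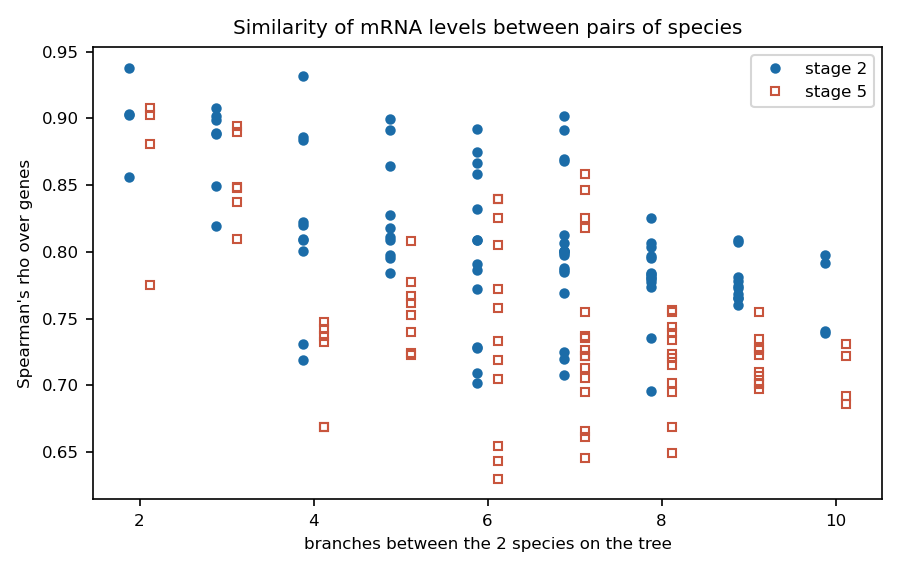
Spearman correlation of mRNA levels over genes for each pair of species, against the number of branches between them on the species tree, at stage 2 (filled circles) and stage 5 (open squares). Points sink from left to right, and stage 5 lies below stage 2 on average (0.748 and 0.804).

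The melanogaster subgroup (6 species with both stages) was compared with the obscura group (3 species) to find mRNAs whose stage change differs between clades. In the obscura group, D. pseudoobscura and D. miranda came wholly from earlier work and were labelled total RNA. Their stage 5 embryos were titled latest5. Without the mixed species they were the whole obscura group. Clade therefore cannot be fully told apart from source, molecule label and staging in the clade comparisons. Tpi, the glycolytic triose phosphate isomerase, had a change of -5.40 ± 0.78 in the melanogaster subgroup, from a median of 104 to 0.727 FPKM, and 2.02 ± 0.30 in the obscura group, from 173 to 625.1 FPKM (SD, n = 6 and 3). The oogenesis gene otu had a change of -3.48 ± 0.68 against 1.98 ± 0.27, the chaperone gene DnaJ-H -1.79 ± 1.36 against 4.25 ± 0.62, CG1890 -4.73 ± 0.94 against 0.70 ± 0.35, and CG30392 -3.76 ± 0.91 against 1.63 ± 0.20. In D. miranda CG1890 was listed at 0 at stage 2 and was at 0.248 FPKM at stage 5, so its small change there is not that of a kept mRNA. In the other direction, danr, which encodes a relative of the dan protein, was at 7.51 ± 0.48 in the melanogaster subgroup, with a median of 181 FPKM at stage 5, and at 0.02 ± 0.02 in the obscura group, with 0.0113 FPKM. The ABC transporter gene Mdr49 was at 6.72 ± 0.80 against 0.18 ± 0.12, CG13894 at 4.59 ± 0.67 against -1.28 ± 0.09, CG12194 at 5.03 ± 1.21 against -0.72 ± 1.01, and CG7900 at 2.37 ± 3.10 against -3.11 ± 1.18. In the obscura group the median of danr was listed at 0 at stage 2. That of Mdr49 was 0.00184 FPKM at stage 2 and 0.0899 FPKM at stage 5. Failed quantification or a wrong gene model would give such values too and was not tested for these genes.

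The difference in stage change, obscura group minus melanogaster subgroup, was 7.42 for Tpi (limma adjusted p = 3.44e-06) and -7.49 for danr (adjusted p = 2.95e-06). In all, 505 genes had a higher and 370 a lower change in the obscura group. The clades did not overlap for 1023 genes (29.3%), against 2.38% for species grouped at random. Species of a clade share ancestry, so random grouping is not a measure of chance here. For 462 of the called genes, the clade means had opposite signs. Without the 4 mixed species in this comparison, and so with fewer species, 122 and 67 genes were called, and CG7900 was not (adjusted p = 0.140). With columns rescaled to the same total, 9 of the 10 named genes lost their call, with Tpi at 7.10 (limma adjusted p = 0.968) and danr at -5.60 (adjusted p = 0.320), while with the total of genes below 100000 all 10 kept it. Without D. persimilis the lower genes numbered 235, and CG7900 was not called without D. persimilis (adjusted p = 0.0816) or D. pseudoobscura (adjusted p = 0.0780).

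**Figure D4:**
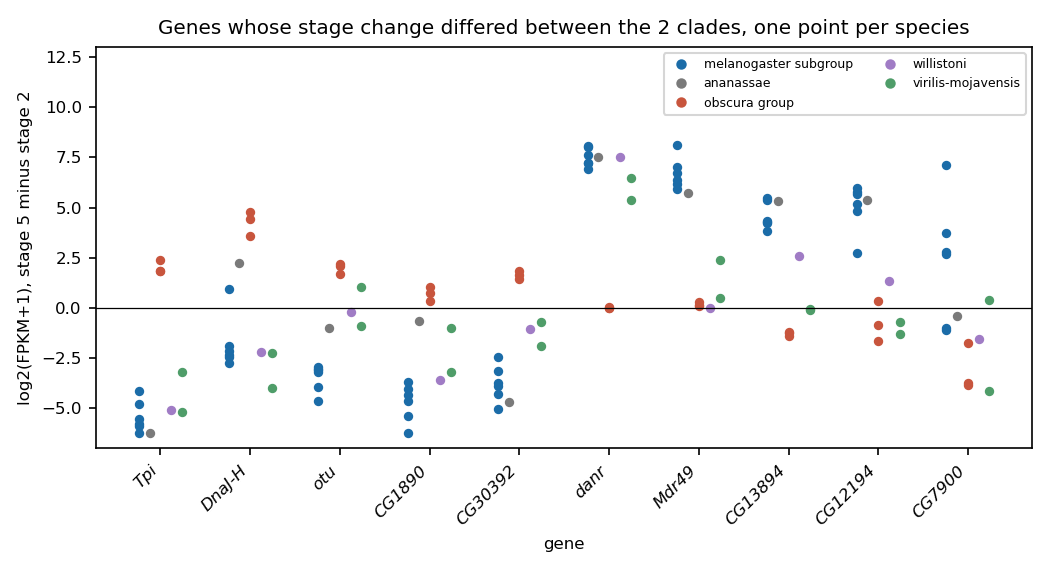
Change from stage 2 to stage 5 on the log2(FPKM+1) scale of the 10 genes named in the clade comparison, 1 point per species, coloured by clade. Tpi rises only in the obscura group among the species shown (2.02 on average), and danr is near 0 only there (0.02).

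Maternal levels of the clades were compared at stage 2, with 7 species of the melanogaster subgroup and 3 of the obscura group. CG12851 was 5.74 higher in the obscura group on the log2 scale (median 46.9 against 0.0460 FPKM), CG13894 was 5.66 higher, CG12194 was 5.04 higher, Vha68-1, a subunit of the vacuolar proton pump, was 4.62 higher (64.8 against 1.60 FPKM) and CG7900 was 4.31 higher. Levels of CG6683 (-4.32), Phm, an enzyme of neuropeptide amidation (-4.09), CG13339 (-4.05), magu (-3.98) and the Rab gene ltd (-4.57, with an SD of 3.30 in the obscura group) were lower there. Here 221 genes were higher and 206 lower in the obscura group. The clades did not overlap for 798 genes (22.8%), against 1.67% for species grouped at random, which ignores shared ancestry. Without the mixed species 113 and 111 genes were called, and CG7900 (limma adjusted p = 0.0831), ltd (adjusted p = 0.170) and magu (adjusted p = 0.0514) were not; ltd was also not called without D. miranda (adjusted p = 0.0502). With columns rescaled to the same total all 10 named genes lost their call, with CG12851 at 5.62 (limma adjusted p = 0.127), and with the total of genes below 100000 all 10 kept it. Gene model lengths differ between annotations and stay in comparisons of levels.

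At stage 5, Tpi was 8.46 higher in the obscura group on the log2 scale (n = 3, against 6 species of the melanogaster subgroup), CG14905 was 5.46 higher, the pentose phosphate enzyme gene Rpi 5.44 higher, CG15093 5.20 higher and Smn, of spliceosome assembly, 5.08 higher. The levels of danr (-7.40), Mdr49 (-6.43), grsm (-6.33), UK114 (-5.39) and CG14512 (-5.17) were lower there. Here 464 genes were higher and 349 lower in the obscura group. The clades did not overlap for 932 genes (26.7%), against 2.38% for species grouped at random, which ignores shared ancestry. Of the genes higher at stage 2 and at stage 5, 74 were shared, where independent lists would share 29.3, and of the lower genes 65 were shared, against 20.6. Without the mixed species 21 and 20 genes were called, and CG15093 (limma adjusted p = 0.0641), UK114 (adjusted p = 0.0538) and Smn (adjusted p = 0.122) were not. With columns rescaled to the same total, 4 of the 10 named genes, CG14905, Smn, Mdr49 and CG14512, lost their call. Without D. pseudoobscura the higher genes numbered 304, and Smn was not called without D. miranda (adjusted p = 0.0754), D. persimilis (adjusted p = 0.0613) or D. pseudoobscura (adjusted p = 0.0607).

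Some mRNAs were missing from, or present in, a single species. At stage 2, Hsc70-4, a heat shock cognate that every other species had at 864 FPKM or above, was at 0.00660 FPKM in D. miranda. There PCNA, the DNA polymerase clamp, was at 0.0381 FPKM (lowest other 145), CG10576 at 0.787 (189) and the proteasome gene Prosalpha3 was listed at 0 (98.9), while in D. mauritiana VhaPPA1-1 was at 4.3e-05 FPKM (67.5). At stage 5, D. miranda had Hsc70-4 at 0.482 FPKM (lowest other 1781), Gbeta13F at 0.193 (244) and PCNA at 0.602 (190), and D. simulans had the actin regulator capt at 0.0379 (126) and Smg5, of mRNA decay, at 1.39e-48 (100). Present in a single species at stage 2 were Hml in D. mojavensis (222 FPKM), FucTA in D. mauritiana (169), drl in D. sechellia (105), and, at values so high that they are doubtful, CanA1 in D. pseudoobscura (1.25e+07) and Prm in D. miranda (1.88e+06). At stage 5 they were Hml in D. mojavensis (946 FPKM), CG17352 in D. mauritiana (156), CG11029 in D. erecta (16.1), Cht7 in D. persimilis (18.1) and CG15725 in D. mauritiana (15.3).

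There were 95 absences and 64 presences at stage 2, and 99 absences and 12 presences at stage 5. D. miranda had 33 of the absences at stage 2 and 25 of those at stage 5. A single value per species has no replicate check, and with thresholds of 0.5 and 10 FPKM the numbers were 49, 39, 44 and 1.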

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

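The tests of ribosomal protein and mixed-species explanations were set down before their values were computed, and those of absent mRNAs and of other splits of the species after the results were seen. The stage changes of 10 genes were picked out because limma's test of the difference separated the stage change of the obscura group from that of the melanogaster subgroup: Tpi (7.42), DnaJ-H (6.04), otu (5.46), CG1890 (5.43), CG30392 (5.39), danr (-7.49), Mdr49 (-6.54), CG13894 (-5.87), CG12194 (-5.76) and CG7900 (-5.48). In addition, a single species lay far from the others of the melanogaster subgroup in 4 of 42 sets, where chance gives about 2.1. These were D. sechellia in the stage change of DnaJ-H (0.92, nearest other -1.91), and D. yakuba in the stage change of CG12194 (2.71, nearest other 4.85), the stage 2 level of CG12194 (-1.82, nearest other -3.93) and the stage 2 level of CG7900 (-0.65, nearest other -3.17).

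Other groupings of the species gave fewer calls than the real ones. The stage comparison had 1760 calls, and 1 of 100 sign flips of the species, the real one, had as many (highest other 1134). The clade comparison of the stage change had 875 calls, reached by 1 of 84 splits (highest other 22), that of stage 2 levels 427, reached by 1 of 100 splits (highest other 3), and that of stage 5 levels 813, reached by 1 of 84 splits (highest other 11). The highest other split of each clade comparison set D. yakuba, D. santomea and D. erecta apart. Any other split puts species of both clades together, which widens the spread within a group. Few calls from the other splits therefore followed from the design and do not test the clade calls.

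The first pattern is the rise of the ribosomal protein genes. A single scaling factor per column could not produce their rise relative to all genes. Their median change exceeded that of all genes by 1.18 in D. yakuba, the lowest species, to 2.24 in D. ananassae. The pseudocount lets a factor move this difference, but it was at least 1.12 without a pseudocount, where a factor cancels, and at least 1.01 with the total of genes below 100000. The rise itself did depend on such factors. The median change of the list was 0.65 with the total of genes below 100000 and 0.09 with the same total. No member was called under either. These genes made up 17.5% to 26.3% of the total of genes below 100000 at stage 2 and 28.3% to 46.1% at stage 5. Dividing by it therefore removes part of their own rise. A few values above 100000 dominate the same total. The lost calls thus do not decide whether scaling produced the calls. A change in the shape of the whole distribution may produce the relative rise too. Quantile normalization took the median change of the list from 2.01 ± 0.32 to 0.04 ± 0.07 (SD, n = 13 species), no more than the 0.05 of all genes. It ended the calls of all members, while the list itself was not tested under it. The calls ended because it gives both stages the same set of values, and these mRNAs sit at the top of the columns at both stages, so the rise is not kept under it. Poly(A) selection stays open, as the lower of the relative changes of D. pseudoobscura and D. miranda, labelled total RNA, was 1.48 against 1.18 for the lowest other species, while their library kit text is that of the others. Zygotic transcription of these genes at stage 5 was not tested apart from these and also stays open.

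The second pattern is the smaller number of clade calls of the stage change without the mixed species, from 875 to 189. D. melanogaster reads in those species stay open as a cause. The 59 other ways of leaving out as many species of each clade gave 156 to 938 calls (median 333), and 4 gave as few. This range, set beforehand as the test, decides nothing, since 57 of these sets leave out mixed species too. The 2 that leave out none gave 351 and 510 calls and are too few to judge by. Whether such reads are present could not be settled at stage 2, where 2 of 3 mixed species correlated better with D. melanogaster than their unmixed relative: D. simulans (0.932) and D. sechellia (0.889) against D. mauritiana (0.886), but not D. santomea (0.892) against D. yakuba (0.900). No biological explanation was tested.

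The third pattern is that of mRNAs missing from 1 species: D. miranda lacked 41, of them 17 at both stages. Low mRNAs near a detection limit do not account for those of D. miranda, where 1.25% of the mRNAs at 20 FPKM or above in every other species were absent (28 of 2240, 95% interval 0.866% to 1.80%, both stages together and taken as independent), against 1.35% of those at 5 to 20 FPKM. In the other species the shares were 0.12% and 0.370%, and that explanation stays open. Failed quantification or a wrong gene model could be the cause and stays open: of the stage 2 absences that could be followed, 62.9% (39 of 62) were below 1 at stage 5 too, between what was set for and against it. The main table holds only genes with a listed ortholog in each species, although D. santomea values are tied to D. yakuba gene identifiers. Elsewhere, loss of a whole gene could therefore be the cause only if its listed ortholog is wrong, which was not tested. A loss of transcription of the gene in that lineage would give the same values and was not tested.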

How the results depend on the processing

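The alternatives with the total of genes below 100000, the wider table for the lists and named genes, and kappa were added after seeing the data; the others were planned. No paired analysis was possible because stage 2 and stage 5 were different embryos and no column belongs to a single embryo, so the stages were paired by species only. For the same reason, leaving out each replicate, leaving out the possibly unfertilized embryo, a replicate block and the comparison of the sexes were not run. Where no cause is given below, the cause was not tested. Maternal genes were shared more than zygotic-only genes under every alternative (difference 0.469 to 0.482 when a species was left out), and species were more alike at stage 2 (0.0533 to 0.0596). The higher and lower genes of the stage comparison numbered 1134 and 626. The higher genes numbered 202 with columns rescaled to the same total, 296 with the total of genes below 100000, 743 with median-centred differences, 635 after quantile normalization, 456 with phylogenetic least squares and 2228 in the wider table, which tests more genes. The lower genes numbered 1537 with the total of genes below 100000, 71 with phylogenetic least squares and 1189 in the wider table. With the same total, which a few values above 100000 dominate, limma called 0 higher and 1 lower gene in the clade comparison of the stage change (49 genes at unadjusted p under 0.05), 1 and 0 at stage 2 (733 genes) and 24 and 15 at stage 5 (564 genes), although changes stayed large (Tpi 7.10, danr -5.60, CG12851 5.62). Without the mixed species, with fewer species per clade, the numbers were 122 and 67, 113 and 111, and 21 and 20. Leaving out 1 species gave 235 (D. persimilis) to 369 lower genes for the stage change and 304 (D. pseudoobscura) to 452 higher genes at stage 5. The median number of cleared genes was 77 at a threshold of 0.5 FPKM and 313 at 5 FPKM. The correlation of similarity with the tree at stage 5 was -0.291 without the mixed species, with 7 species. With an estimated correlation 3 lists were called higher and 1 lower, against 6 and 4 with the preset one. The direction of the respiratory chain list, down in the main table, turned up with 1 mean per clade (camera adjusted p = 0.717, not called) and in the wider table (adjusted p = 2.05e-06), which holds 60 of its genes instead of 3. With thresholds of 0.5 and 10 FPKM there were 49 absences and 39 presences at stage 2, and 44 and 1 at stage 5. Of the named genes, these changed sign. With the same total: slam -0.016, cact -0.30, Stat92E -1.63, CycE -1.0, Hsc70-4 -0.56, msl-3 -1.37, Fcp3C -0.077, mRpS6 -0.47, mRpS33 -0.53, bonsai -0.53, mRpS2 -0.56, Prosbeta7 -0.033, Prosbeta4 -0.52, Prosbeta1 -0.47, Prosbeta2 -0.58, SdhC -0.64 and SdhB -1.27. With the total of genes below 100000: Stat92E -1.25, CycE -0.52, msl-3 -1.0, Fcp3C -0.14, Prosbeta2 -0.0096, SdhC -0.077 and SdhB -0.79. After quantile normalization: Stat92E -0.89, CycE -0.43, Hsc70-4 -0.29, msl-3 -0.12, Fcp3C -0.12, Prosbeta4 -0.091, Prosbeta2 -0.20 and SdhB -0.14. With median-centred differences: Stat92E -0.36, msl-3 -0.14 and Fcp3C -0.17. Without the mixed species Stat92E was at -0.035, and leaving out 1 species took it from -0.050 (D. mojavensis) to 0.20 (D. mauritiana), with -0.012 without D. virilis. In the wider table, leaving out 1 species took Cp7Fa from -0.21 (D. ananassae) to 0.12 (D. sechellia), with 0.013 without D. mojavensis, 0.0095 without D. persimilis and 0.028 without D. pseudoobscura. Not called in the main table, but called under an alternative, were tral, bel, CycE, SdhA and SdhB (SdhB at 1.03 with 1 mean per clade; limma adjusted p = 0.0402). In all, 17 of the 76 genes named in the stage comparison changed sign under some alternative other than leaving out 1 species, and 26 lost their call under one. The depth of the libraries is unknown, so how far it limits the low values could not be told.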

Other observations

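Some mRNAs moved in opposite directions in different species. There were 200 such genes (5.72% of those tested), at least 2-fold higher at stage 5 in at least 3 species and at least 2-fold lower in at least 3 others, and the genes named here were chosen after their values were seen. CG7255 ran from -3.83 to 7.20 over the 13 species, CG5567 from -5.51 to 5.20 (SD 3.18), Ndae1 from -4.58 to 4.17 (SD 2.95), the sodium-proton exchanger gene Nhe2 from -1.99 to 5.63 (SD 2.65) and the small heat shock protein gene Hsp67Ba from -5.86 to 2.32 (SD 2.64).

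Few maternal mRNAs dropped below 1 FPKM everywhere. E23 had medians of 43.7 FPKM at stage 2 and 0.275 FPKM at stage 5, and CG16711 of 14.7 and 0.0514 FPKM. Besides these, Pdp1 was cleared in 12 of 13 species, the nuclear receptor gene Hnf4 in 11 and the growth regulator foxo in 10. The ribosomal protein genes made up 17.5% (D. persimilis) to 26.3% (D. virilis) of the total FPKM of genes below 100000 at stage 2, and 28.3% (D. yakuba) to 46.1% (D. ananassae) at stage 5. Values of 100000 FPKM or above were listed for 9 genes in 8 columns.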
